A study of Cyprinodon variegatus with 4 samples.

How the data were processed

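Whole larvae of the sheepshead minnow were sequenced as 4 RNA libraries, 1 each for untreated control, surfactant control (Tween 80 at 0.001%), PET microfibres at 10 mg/L and PET microfibres at 100 mg/L. Per the labels' protocols, exposure lasted 10 days, total RNA was prepared with a column kit, and libraries were made by standard Illumina protocols. The labels give the developmental stage as 72 h after fertilization, which was read here as the start of exposure. Whether the fibre suspensions also held Tween 80 is not given for each sample in the labels; the surfactant control was taken as the reference of the PET libraries because the labels' protocols name it beside the fibre exposures. Each group held 1 library, so no replicate error exists, and no p-value or standard error was computed.

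The deposited table gave expression as FPKM (fragments mapped to a contig, scaled to its length and to the fragments mapped in the library), per the file headers, in 1 column per library for 257521 contigs. The submitters' processing notes name bcl2fastq 2.20.0.422, RSEM and Bowtie, with no version for RSEM or Bowtie. How the contigs were assembled and annotated is not given in the sources used here. Annotations, of the kind used by Swiss-Prot, stood in the table for 24404 contigs, and some name proteins of organisms other than fish. None of the contig names matched a reference table of gene names for the C_variegatus-1.0 assembly (0 matches), so gene names come from the table alone, and no genome was used here. The contig lengths listed in the table did not scale with the FPKM steps and were not used. FPKM keeps no read counts, so the counting error of a single value is unknown. In contigs with a mean under 3 FPKM the ratios between libraries heaped at fixed steps, which gave the relative depths reported.

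Values were used as deposited. Log2 ratios were taken of FPKM plus a pseudocount of 0.5, which understates the ratio of contigs with low values, and a contig listed at 0 in a library has no fold against it. Contigs with a mean of at least 1 FPKM over the 4 libraries were kept (45298), and a contig was counted as higher or lower at a ratio of at least 2-fold. An exact 0 can be a failed estimate of an isoform's share rather than absence, so such contigs are described as listed at 0. The 6 comparisons between libraries, the counts of contigs past 2-fold from both libraries without fibres, the correlation of the PET ratios and the gene list medians were fixed before the data were examined, as were the named genes and the gene lists.

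Named genes followed a fixed rule. For each PET concentration they are the 12 highest and 12 lowest annotations among those at least 2-fold from both libraries without fibres, ranked by the smaller ratio; for the surfactant control against the control, the 8 highest and 8 lowest; between the concentrations, the 5 highest and 5 lowest; and per list described, up to 4 members with the largest ratio of PET 100 mg/L to surfactant control. The lists of the corpuscles of Stannius, of Merkel cells and of epithelial calcium transport, which the title points to, are described in full. Where several contigs carried 1 annotation, the contig with the highest mean stands for it. Its other contigs can go the other way. For annotations named by their ratios between libraries, FPKM summed over all contigs of the annotation is therefore described as well. This alternative was chosen after the data were seen. List members have the sum in some cases and are otherwise given by the main contig alone. A few genes that this rule names are not reported here. Other genes named were chosen after their values were seen: CEBPB in the PET libraries, CDK1, TOP2A, MEP1B, RPL5, and those of the closing observations.

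The gene lists, 33 with 659 members, covered cell types of a whole larva, endocrine axes, ion transport, tissue damage, stress and metabolism. A contig belonged to a member if its symbol equalled the member's, with or without a paralogue suffix, or if its description began with the member's full name. This rule also took in other proteins whose names begin alike, 88 of 713 pairs of list and contig. The results are given by the rule as fixed, and again, as an alternative chosen after the data were seen, without those pairs, where that changes what is reported. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins (seed 1); a percentile outside the central 95% is a description of these libraries, not a test of the treatment. Simulated references for the correlation came from 100 sets of unchanged libraries.

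The computations were checked on simulated data. The simulation was of PET 100 mg/L against the surfactant control, with 45298 contigs. Of 100 contigs changed 8-fold, 99.0% were past 2-fold in the right direction. Of 100 changed 2-fold, 54.0% were, as these sit at the threshold. Changes were added to log2 values that already held the pseudocount, and no contig was listed at 0. Recovery of contigs with low values in the data would therefore be lower. In the same simulation 21.8% of unchanged contigs were past 2-fold; its noise was drawn from a normal distribution with the observed SD, which overstates the share in the data. Alternatives tried were median-of-ratios and upper quartile scaling, pseudocounts of 0.1 and 1, no filter, a mean of at least 5 FPKM, a 4-fold threshold, the untreated control as the reference, and 1 contig per annotation. Added after the data were seen were a mean of at least 20 FPKM and FPKM summed over the contigs of an annotation. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.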

Results

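RNA was sequenced from whole larvae of the sheepshead minnow (Cyprinodon variegatus), a small estuarine fish used in toxicity testing. There were 4 libraries, 1 per group: untreated control larvae, a surfactant control given Tween 80 at 0.001%, and larvae exposed to microfibres of polyethylene terephthalate (PET, the polyester of textiles and bottles) at 10 or 100 mg/L. Exposure lasted 10 days, and the stage given in the labels, 72 h after fertilization, was read as its start. The series title names Merkel cells, the touch receptor cells of the skin, and the corpuscles of Stannius, the fish glands that secrete the calcium-lowering hormone stanniocalcin, as putative targets of the fibres. Expression was given as FPKM for 257521 assembled contigs, of which 24404 carried a protein annotation. With 1 library per group, no difference reported here has a replicate check; all values compare libraries, and no p-value was computed.

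The FPKM of a library summed to 1039707 in the control, 1064942 in the surfactant control, 1080208 at 10 mg/L PET and 1057890 at 100 mg/L. The numbers of contigs above 0 were 150173, 143907, 151673 and 152374, in the same order. Read counts were not used here, so absolute depth is unknown. The spacing of the lowest values put the depth of the surfactant control at 78.5% of that of the control, PET 10 mg/L at 84.1% and PET 100 mg/L at 78.5%. Contigs with a mean of at least 1 FPKM over the 4 libraries entered the comparisons, 45298 in all, 10011 of them annotated. Across these contigs, which are not independent replicates, the Pearson correlation of log2 values between any pair of libraries lay between 0.843 and 0.873.

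The hepatocyte, lens, and complement and acute phase lists set the surfactant control apart from the untreated control. The hepatocyte list was higher in the surfactant control, with a median log2 ratio of 0.28 over 27 contigs, above 99.96% of random lists of the same size and expression. Fibrinogen gamma chain (fgg, a clotting protein made by the liver) was at 123 FPKM in the control and 150 in the surfactant control, and tryptophan 2,3-dioxygenase (tdo2) at 0.61 and 2.80. Lens crystallins were also higher, with a median of 0.26 over 22 contigs (percentile 99.99); gamma-crystallin M2 was at 4759 FPKM in the control and 5940 in the surfactant control, and gamma-crystallin M3 at 771 and 962. The complement and acute phase list had a median of 0.15 (percentile 98.2).

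The list of matrix metalloproteinases and wound response was lower in the surfactant control, with a median of -0.14 over 18 contigs (percentile 1.51). The immediate-early transcription factor EGR1 was at 39.7 FPKM in the control and 23.2 in the surfactant control, and the stress-induced factor ATF3 at 9.36 and 5.24. Without 1 contig whose description named another protein, this list lay at percentile 2.60, inside the central 95%. The other 28 measured lists lay inside the central 95% of random lists. If contigs varied independently, 1.6 of the 32 measured lists would lie outside it at random. Random lists drew contigs singly, while the gene lists hold several contigs of some annotations and genes that can vary together. More lists could therefore lie outside without any treatment effect. At single contigs, 3559 were at least 2-fold higher and 2993 at least 2-fold lower in the surfactant control. Of these 6552 contigs, 93.3% had a mean under 5 FPKM and 56.1% were listed at 0 in either library. Taking the main contig of each annotation (that with the highest mean), the 8 annotations with the highest ratios were SPRY1, an inhibitor of growth factor signalling (0 FPKM in the control and 16.4 in the surfactant control), LGR5 (0 and 7.04), histone H3.1 (0 and 6.53), NPFFR1, TBC1D1 and FAM45A (each 0 and 5.77), KMT2E (0 and 5.50) and a probable trans-2-enoyl-CoA reductase (0 and 4.79). Summed over all contigs of the annotation, 7 of the 8 were still at least 2-fold higher, but SPRY1 was at 14.7 FPKM in the control and 16.4 in the surfactant control. The 8 with the lowest ratios were all listed at 0 in the surfactant control at their main contigs: PABPC4 (39.9 FPKM in the control), the liver and inflammation transcription factor CEBPB (20.1), the putative uncharacterized protein ART2 (13.3), an uncharacterized protein matched to Plasmodium (7.39), BTN2A1 (7.39), Xfin (6.06), DKC1 (5.77) and PCDHA1 (5.64). By the sums 6 of these 8 were at least 2-fold lower and 3 were at 0; BTN2A1 was at 9.58 and 5.65 FPKM and DKC1 at 7.28 and 4.32. CEBPB was at 14.8 FPKM at 10 mg/L PET and at 18.1 at 100 mg/L.

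**Figure D1:**
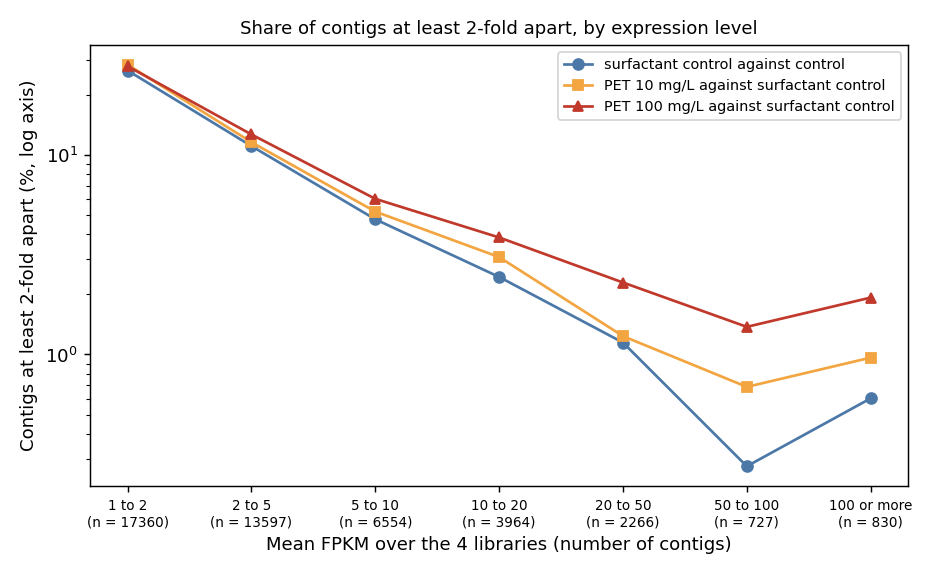
Percent of contigs at least 2-fold apart (log axis) against the mean FPKM of the contig over the 4 libraries; each line joins the values of 1 comparison between single libraries. Between the control and the surfactant control the share was 26.5% from 1 to 2 FPKM and 0.60% at 100 FPKM or more, and between PET 100 mg/L and the surfactant control 27.9% and 1.93%.

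Of the genes that the title points to, stanniocalcin was lowest in the surfactant control and highest at 100 mg/L PET. Its main contig was at 8.49 FPKM in the control, 3.17 in the surfactant control, 4.65 at 10 mg/L and 10.99 at 100 mg/L. PET 100 mg/L was therefore higher than the surfactant control by a log2 ratio of 1.65 but higher than the untreated control by 0.35, and PET 10 mg/L was below the untreated control, at -0.80. CYP24A1, which inactivates vitamin D, had the same order of libraries at its main contig, at 17.3, 9.92, 12.2 and 20.3 FPKM. Summed over its 3 contigs CYP24A1 was at 23.55, 17.89, 17.18 and 26.55 FPKM, lowest at 10 mg/L, whereas stanniocalcin summed to 8.95, 3.36, 5.33 and 11.48. Stanniocalcin-2 was at 2.06, 0.95, 3.05 and 1.67 FPKM at its main contig and 3.65, 2.57, 3.05 and 2.43 in sum, and calcitonin gene-related peptide (CALCA) at 4.66, 4.56, 5.48 and 5.91.

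The list of the corpuscles of Stannius and calcium-regulating hormones had 7 contigs past the filter and medians of -0.05 for surfactant control against control (percentile 37.8), 0.24 for PET 10 mg/L against surfactant control (percentile 93.5) and 0.34 for PET 100 mg/L against surfactant control (percentile 94.2), all inside the central 95%. Of these contigs, 2 were annotated as other proteins. With the 5 that remain, the medians were -0.77 (percentile 0.14), 0.29 (percentile 94.1) and 0.58 (percentile 98.5). Against the untreated control they were -0.21 at 10 mg/L (percentile 6.56) and 0.22 at 100 mg/L (percentile 76.8), inside the central 95%. The calcium-sensing receptor CASR matched 34 contigs, none of them past the filter, with summed values of 6.89, 7.83, 7.78 and 11.2 FPKM in the order control, surfactant control, 10 mg/L and 100 mg/L. The higher sum at 100 mg/L rests largely on TR213209|c0_g1_i1 and TR27478|c0_g1_i1, each at 2.22 FPKM there and listed at 0 in the other libraries. In the same order TR137655|c0_g1_i1 was at 0, 0.92, 1.77 and 0 FPKM. Whether all these contigs are of 1 gene was not tested. No contig was matched to STC1 under that name or to TRPV6.

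Epithelial calcium transport genes were led by S100G (calbindin-D9k, a calcium-binding protein), at 460 FPKM in the control, 451 in the surfactant control, 570 at 10 mg/L and 690 at 100 mg/L. The sodium/calcium exchanger SLC8A1 was at 2.89, 4.59, 4.28 and 3.63 FPKM, and the plasma membrane calcium pumps ATP2B1 and ATP2B3 at 9.53 and 9.08 at 100 mg/L against 10.9 and 7.45 in the surfactant control. ATP2B2 was at 9.58 FPKM against 8.40, and calretinin (CALB2) at 71.5 against 67.5. The 9 contigs of the list had a median of 0.10 at 10 mg/L (percentile 79.4) and 0.27 at 100 mg/L (percentile 95.3), both inside the central 95%.

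Merkel cell markers as a list were not set apart in either PET library. The 23 contigs had a median of 0.05 at 10 mg/L against the surfactant control (percentile 66.3) and 0.08 at 100 mg/L (percentile 43.9), the latter at 0 after median-of-ratios scaling. The mechanosensitive channel PIEZO2 was at 2.25, 2.31, 1.59 and 1.88 FPKM in the order control, surfactant control, 10 mg/L and 100 mg/L at its main contig, and at 4.21, 2.57, 1.98 and 3.41 in sum. RAB3C was at 7.87, 3.50, 4.87 and 6.73 (in sum 9.74, 8.85, 8.21 and 11.62), POU4F3 at 0.58, 2.33, 0 and 1.45, FGF13 at 6.61, 6.54, 5.84 and 8.61, and chromogranin A at 9.81, 9.87, 10.8 and 12.4. Keratin 8, found in many simple epithelia, was at 1692, 1649, 1706 and 2028 FPKM and keratin 18 at 291, 304, 314 and 298. DDC, PENK and the vesicular glutamate transporter slc17a6b were at 4.68, 2.56 and 4.25 FPKM at 100 mg/L against 3.86, 2.76 and 4.15 in the surfactant control. ATOH1, the transcription factor that specifies Merkel cells, matched 2 contigs, neither past the filter, with summed values of 0.88, 0.21, 0.29 and 1.17 FPKM. ISL1 was listed at 0 except at 100 mg/L (0.67 FPKM), and no contig was matched to SOX2. In RNA of whole larvae the contigs of the list can also come from other cells. The list median therefore cannot show whether Merkel cells changed.

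**Figure D2:**
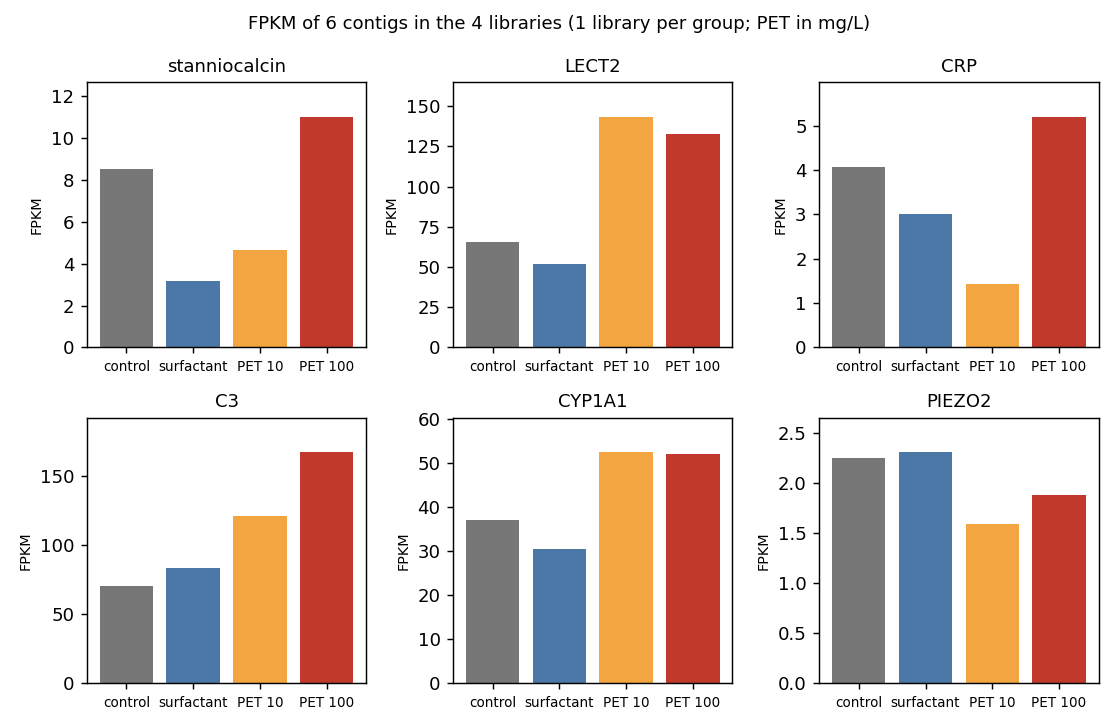
FPKM (bars, from 0) of the main contigs of stanniocalcin, LECT2, C-reactive protein (CRP), complement C3, cytochrome P450 1A1 (CYP1A1) and PIEZO2 in the control, the surfactant control, and PET at 10 and 100 mg/L, with 1 library per bar and no error bars. Stanniocalcin ran from 3.17 FPKM in the surfactant control to 10.99 at 100 mg/L, and LECT2 from 51.6 in the surfactant control to 143 at 10 mg/L.

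At 10 mg/L PET, the median of the complement and acute phase list was higher than in the surfactant control. LECT2, a liver-secreted chemotactic factor of the acute phase, was at 143 FPKM against 51.6, and complement C3 at 121 against 83.2, whereas C-reactive protein was at 1.43 against 3.01. In sum, C3 was at 148 FPKM against 111 and C-reactive protein at 4.48 against 7.94. The 14 contigs of the list had a median of 0.23 (percentile 99.5), with 6 at least 1.25-fold higher and 2 at least 1.25-fold lower. The photoreceptor list was lower, with a median of -0.09 over 33 contigs (percentile 1.09). Peripherin-2, a structural protein of photoreceptor discs, was at 14.8 FPKM against 18.6 and cone arrestin (ARR3) at 100.0 against 118, while GUCA1A was at 9.54 against 7.62 and PDE6C at 1.33 against 0.87. Without 1 contig of another protein this list lay at percentile 4.08, and against the untreated control at percentile 21.0, both inside the central 95%.

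The heat shock and unfolded protein response list was lower at 10 mg/L, with a median of -0.14 over 35 contigs (percentile 0.11). This call rested on contigs of HSPA12A, HSPA12B and HSPA4, other proteins whose names begin like that of a member. The 20 contigs that remain without them had a median of 0.01 (percentile 46.0). The inducible chaperones HSP70 (hsp70) and HSP30 were at 2.73 and 3.03 FPKM against 1.21 and 1.56 in the surfactant control; summed over its 4 contigs, hsp70 was at 3.70 against 3.19. Cell cycle genes, including TOP2A (8.28 FPKM against 9.41) and CDK1 (16.96 against 18.2), had a median of -0.14 (percentile 3.37), and of -0.19 (percentile 1.32) when 4 contigs of other proteins were left out.

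Against both libraries without fibres, 1918 contigs were at least 2-fold higher and 1510 at least 2-fold lower at 10 mg/L. By the same rule the surfactant control was higher than the control and PET 10 mg/L in 1475 contigs and lower in 1756, and the control differed from the other pair in 964 and 1772. Among annotations, 60 were higher and 59 lower by that rule. The 12 highest were listed at 0 in both the control and the surfactant control at their main contigs: PKD1 (17.2 FPKM), BTAF1 (12.2), the cytokine signalling inhibitor CISH (10.1), TRIM27 (7.09), GBF1 (5.45), a kinase matched to a giant virus (4.63), TRIM69 (4.42), PPP1R21 (4.33), TMEM98 (4.23), RBM42 (4.23), GOT2 (4.03) and DHX8 (4.03). Of these, 11 were listed at 0 at 100 mg/L as well; the exception was TRIM27, a ubiquitin ligase of the tripartite motif family, at 10.7 FPKM. Summed over all contigs of the annotation, all 12 were still at least 2-fold higher than in both, and 4 were at 0 in both. Among the 12 lowest by main contig, the cytoskeletal cross-linker alpha-actinin-1 (ACTN1) was at 103 FPKM in the control, 112 in the surfactant control, 17.8 at 10 mg/L and 178 at 100 mg/L, and the prefoldin-like protein UXT at 13.01, 11.7, 0.83 and 11.4. The other 10 were listed at 0 at 10 mg/L: a tubulin alpha-1 chain (5.39 FPKM in the surfactant control), RAPGEF1 (3.06), MSI1 (5.04), PCDHA13 (2.18), ZNF84 (2.58), MTIF2 (2.89), TRIM33 (1.97), ZNF629 (7.88), PCDHGA7 (4.76) and UGGT1 (2.34). By the sums 8 of the 12 were at least 2-fold lower and 4 were at 0. The sums of ACTN1 were 236, 245, 145 and 294 FPKM and those of UXT 13.7, 13.1, 11.9 and 15.6, under 2-fold from both libraries without fibres; PCDHGA7 and UGGT1 were not past 2-fold either. Against the surfactant control alone, 3852 contigs were at least 2-fold higher and 3150 lower, 7002 in total, beside 6552 between the libraries without fibres.

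At 100 mg/L PET, the complement and acute phase list was higher than in the surfactant control, and the medians of the muscle, epidermal and mitochondrial lists were lower, by small steps in the values as deposited. At their main contigs, complement C3 was at 167 FPKM against 83.2, LECT2 at 133 against 51.6, and C-reactive protein at 5.20 against 3.01. Summed over its 7 contigs, C3 was at 198 FPKM against 111, a log2 ratio of 0.83. C-reactive protein, over 5 contigs, was at 9.59 against 7.94, a log2 ratio of 0.26. The median of the complement and acute phase list was 0.42 (percentile 99.96), against 0.08 for random lists, with 9 of its 14 contigs at least 1.25-fold higher and 1 lower. The median of all contigs was itself 0.10 higher at 100 mg/L than in the surfactant control and 0.11 higher than in the control, and median-of-ratios scaling moved it to 0, a shift of -0.11 in the latter. For lists set apart from the surfactant control at 100 mg/L, the median of random lists is therefore given as well. Other list medians at 100 mg/L hold this shift too and are to be read by their percentiles, as random lists carry it alike. After that scaling the complement median was 0.30. The medians of the skeletal muscle, keratinocyte and respiratory chain lists were then -0.232, -0.275 and -0.186, further below 0 than as deposited.

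The skeletal muscle list had a median of -0.11 over 70 contigs, lower than each of the 10000 random lists, whose median was 0.06, but 10 contigs were at least 1.25-fold higher and 15 at least 1.25-fold lower. Titin was at 41.4 FPKM against 57.7, fast troponin I (TNNI2) at 516 against 678 and tropomyosin alpha-1 at 5137 against 6648, while skeletal alpha-actin was at 541.2 against 390.8. Keratinocyte genes had a median of -0.15 over 20 contigs (percentile 0.15; random lists 0.06), with 1 at least 1.25-fold higher and 4 lower. Keratin 13 was at 4282 FPKM against 5695, the epidermal master regulator TP63 at 1.47 against 4.04, transglutaminase 1 (TGM1) at 4.73 against 6.85 and plakophilin-3 at 48.5 against 61.8. With no filter this list lay at percentile 18.98. The mitochondrial respiratory chain list had a median of -0.06 over 21 contigs (percentile 2.11; random lists 0.04), with 0 at least 1.25-fold higher and 1 lower. ADP/ATP translocase 1 (SLC25A4) was at 722 FPKM against 830 and COX5A at 615 against 678, whereas ATP5O was at 348 against 316. With 1 contig per annotation this list lay at percentile 18.3.

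The list of gluconeogenesis, fasting and growth had a median of 0.25 over 32 contigs at 100 mg/L (percentile 98.3; random lists 0.10). Insulin was at 5.30 FPKM against 2.32, but PCK1, a gluconeogenic enzyme, was listed at 0 against 1.33, the muscle ubiquitin ligase TRIM63 was at 3.44 against 5.51 and IRS2 at 5.72 against 7.87. The list lay inside the central 95% with contigs of other proteins left out (percentile 97.48), with a mean of at least 5 FPKM (percentile 96.8) and with 1 contig per annotation (percentile 95.5). Thyroid axis genes had a median of -0.28 over 9 contigs (percentile 0.72; random lists 0.09), with DIO2, the enzyme that activates thyroid hormone, at 2.32 FPKM against 3.22, while DIO3 was at 23.2 against 19.7. With 1 contig per annotation the thyroid median was 0.00 (percentile 23.5), and with a mean of at least 5 FPKM it was 0.05.

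Several lists of stress, tissue damage, ion transport and cell types were not set apart at 100 mg/L. Xenobiotic metabolism had a median of 0.07 (percentile 48.9), although the dioxin-inducible enzyme CYP1A1 was at 52.1 FPKM against 30.5 in the surfactant control and 37.0 in the control, and at 52.5 at 10 mg/L. UGT2A1 was at 9.01 FPKM against 5.70 in the surfactant control, and AHRR at 0.90 against 2.04 in the control at its main contig but at 5.47 against 3.78 in sum. Oxidative stress defence had a median of 0.05 (percentile 36.2), innate immunity and inflammation 0.15 (percentile 74.9), mucous and goblet cells 0.11 (percentile 66.4), ionocytes 0.18 (percentile 94.9) and the exocrine pancreas 0.17 (percentile 96.6); the first and the xenobiotic list were below 0 after median-of-ratios scaling, at -0.07 and -0.04. The prostaglandin synthase PTGS2 was at 1.56 FPKM against 0.14, and the water channel AQP3 at 9.66 against 17.2 at its main contig and 24.4 against 27.3 in sum. The 14 egg yolk and egg envelope genes had no contig past the filter.

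Against both libraries without fibres, 1965 contigs were at least 2-fold higher and 1427 at least 2-fold lower at 100 mg/L, with 60 annotations higher and 66 lower. By the same rule with PET 100 mg/L in the pair, the surfactant control was higher in 1434 contigs and lower in 1815, and the control in 942 and 1822. The 12 highest annotations were listed at 0 in the control and the surfactant control at their main contigs. They included TMEM108 (14.1 FPKM), TRIM27 (10.7), the meiotic recombination factor PSMC3IP (7.93), an NADH dehydrogenase matched to a slime mould (6.14), USP37 (3.97), SRFBP1 (3.21), GSPT1 (3.21), a V-type proton ATPase subunit E (2.61), TRIM71 (2.54), SGK1-A (2.51) and an ADP,ATP carrier protein (1.96). Of the 12 annotations, 3 were listed at 0 at 10 mg/L too. By the sums 11 of the 12 were at least 2-fold higher than in both and 7 were at 0 in both; the exception was GSPT1, at 1.22 and 1.60 FPKM without fibres against 3.21. The main contigs of the 12 lowest were all listed at 0 at 100 mg/L and included those of FRY (9.16 FPKM in the surfactant control), RTL1 (3.42), HSDL2 (3.34), a gag-pol polyprotein (5.92), RPAP2 (4.25), the muscle Z-disc protein nexilin (NEXN, 2.70), RAPGEF1 (3.06), DDX6 (5.31), MTIF2 (2.89), TRIM33 (1.97) and ZNF629 (7.88). By the sums 7 of the 12 were at least 2-fold lower than in both and 4 were at 0. FRY summed to 11.97 FPKM at 100 mg/L against 21.94 in the surfactant control, RTL1 to 4.56 against 10.06 and DDX6 to 1.98 against 7.13, each under 2-fold below the control. Gag-pol summed to 11.09 FPKM and ZNF629 to 6.13, above the control at 10.34 and 4.76 and below the surfactant control at 18.55 and 10.34. Against the surfactant control alone, 4158 contigs were at least 2-fold higher and 3030 lower, 7188 in total. Among the 3823 contigs with a mean of at least 20 FPKM, a level chosen after the data were seen, 78 were past 2-fold (33 higher and 45 lower), beside 41 at 10 mg/L and 33 between the libraries without fibres.

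**Figure D3:**
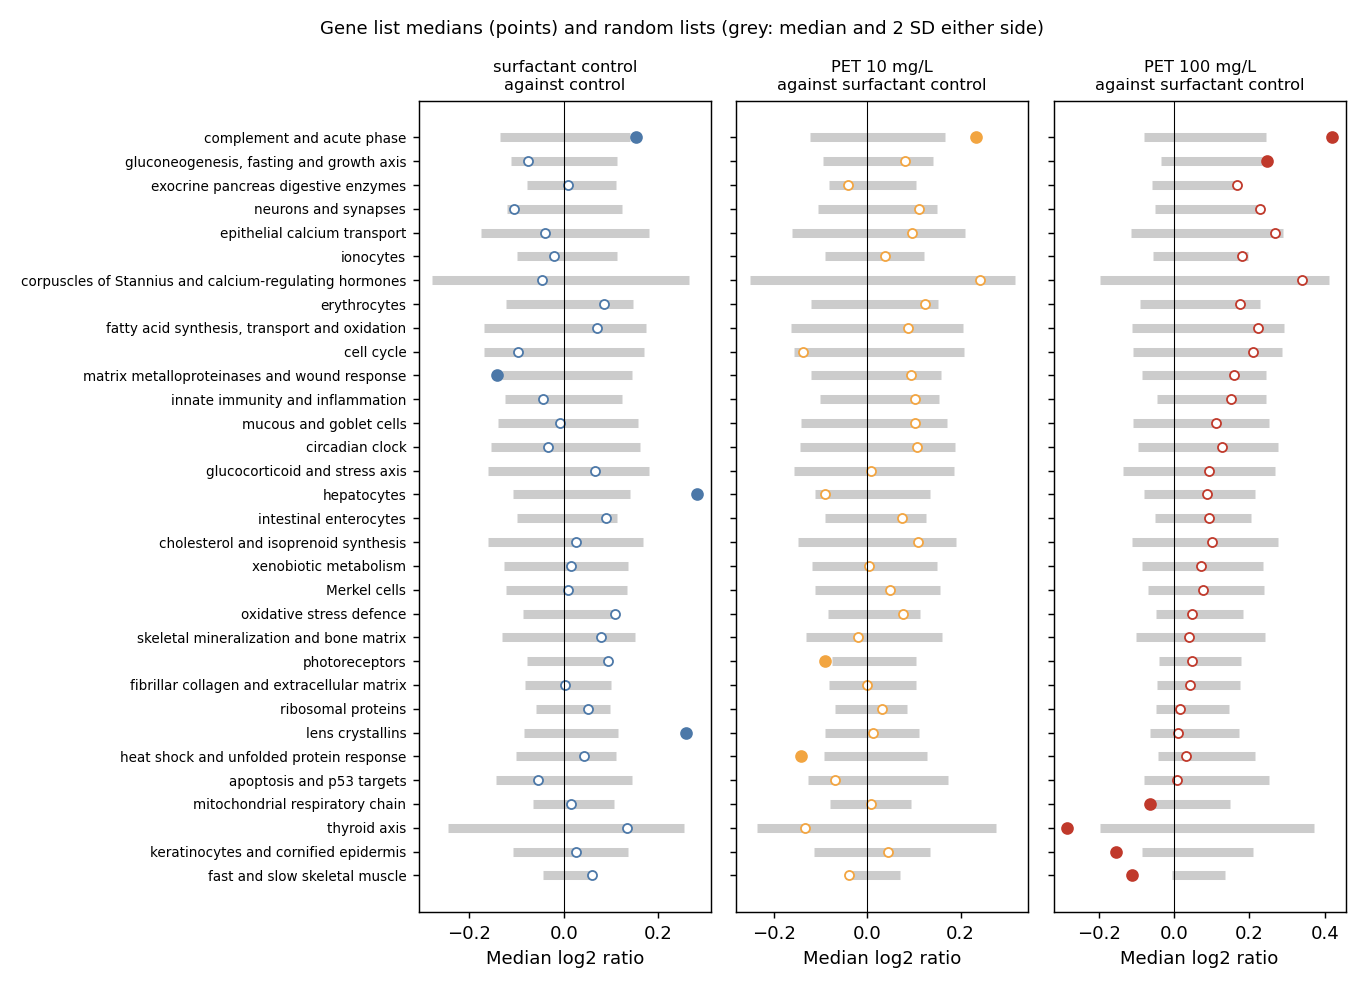
Median log2 ratio (x axis) of the contigs of each of 32 gene lists for the surfactant control against the control and for each PET library against the surfactant control; filled points lie outside the central 95% of 10000 random lists, and grey bars span 2 SD either side of the random lists' median. Among the lists as plotted, by the rule as fixed, complement and acute phase is the highest at 100 mg/L, at 0.42, and its sign is kept under median-of-ratios scaling, at 0.30.

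When the untreated control was the reference, the median of the complement and acute phase list was again higher, at 0.46 at 10 mg/L and 0.61 at 100 mg/L, each at percentile 100. Hepatocyte genes were higher too, at 0.25 (percentile 99.7) and 0.30 (percentile 99.2), as they were in the surfactant control. Lens crystallins were higher at 0.24 (percentile 99.9) and 0.23 (percentile 98.8), and intestinal enterocyte genes at 0.19 (percentile 99.2) and 0.26 (percentile 98.96), with meprin A subunit beta (MEP1B) at 40.6 FPKM in the control, 55.9 at 10 mg/L and 63.2 at 100 mg/L. Skeletal muscle was lower at -0.03 (percentile 2.33) and -0.04 (percentile 0.08). At 100 mg/L, cholesterol and isoprenoid synthesis was higher at 0.32 (percentile 98.5), keratinocytes were lower at -0.09 (percentile 1.42) and the respiratory chain was lower at -0.08 (percentile 1.075). At 10 mg/L, the cell cycle list was lower at -0.18 (percentile 1.30) and the heat shock list at -0.09 (percentile 1.76), the latter at 0.01 (percentile 37.8) without the other proteins. The thyroid and gluconeogenesis lists at 100 mg/L lay inside the central 95% against the untreated control, at -0.11 and 0.08. The counts past 2-fold were 4078 higher and 2713 lower at 10 mg/L, and 4294 higher and 2629 lower at 100 mg/L.

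LECT2, TRIM27 and ART2 were the 3 annotations at least 2-fold from both libraries without fibres at both concentrations by summed FPKM, at a mean of at least 5. LECT2 was at 65.4 and 51.6 FPKM without fibres and at 143 and 133 with them; the main contig of TRIM27 was listed at 0 without fibres and at 7.09 and 10.7 with them, and its 8 contigs summed to 3.58 and 2.78 FPKM without fibres and 16.1 and 14.4 with them. ART2, annotated only as a putative uncharacterized protein, summed to 15.06 and 5.53 FPKM without fibres and 1.11 and 0.33 with them. At lower levels RAPGEF1 summed to 2.61 and 3.42 FPKM without fibres and 0.11 and 0.60 with them, and MTIF2 and TRIM33, of 1 contig each, were listed at 0 at both concentrations. In all, 697 contigs were at least 2-fold higher and 452 at least 2-fold lower in both PET libraries than in both libraries without fibres, where independent lists would share 83.2 and 47.6; 55 and 62 contigs went in opposite directions. Other pairings of the 4 libraries gave similar totals, 1108 and 1132 beside 1149. Lists set against the same references are not independent. Most of the excess over independent lists is therefore not particular to the PET pair.

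The log2 ratios of the PET libraries against the surfactant control correlated across contigs with a Pearson r of 0.491, where unchanged libraries simulated against 1 shared reference gave 0.50. The covariance was 0.447 against 0.387 simulated. With the untreated control shared instead, r was 0.424 and the covariance 0.341, below the simulated values. With that control shared, the surfactant control went with PET 100 mg/L about as closely (r 0.431, covariance 0.338). With PET 10 mg/L the values were 0.417 and 0.331. The simulation gave every library the same noise, so a covariance above it is not by itself agreement of the PET libraries. With a different reference for each concentration, r was 0.011 and 0.003. Among the 14341 contigs with a mean of at least 5 FPKM, r was 0.554 against 0.50 simulated, and 0.071 and 0.092 with references apart. The covariance with the surfactant control shared was 0.116 against 0.093. With the control shared, r there was 0.521 for the PET pair. It was 0.434 and 0.464 for the surfactant control with PET 100 and PET 10 mg/L. Among the 3823 with a mean of at least 20 FPKM, r with the surfactant control shared was 0.461 against 0.503 simulated, with a covariance of 0.048 against 0.038, and r was 0.141 and 0.068 with references apart. With the control shared, r in the same order of pairs was 0.473, 0.441 and 0.425. Contigs are not independent replicates, and no more than 1 library stood behind each end of these ratios.

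From 10 to 100 mg/L, the list medians of the exocrine pancreas, liver and photoreceptors were higher, and those of the epidermis, muscle and ribosome lower. Exocrine pancreas enzymes had a median of 0.20 over 26 contigs (percentile 99.75; random lists 0.04), with elastase-1 at 1260 FPKM at 10 mg/L and 1554 at 100 mg/L and chymotrypsin B at 9.10 and 11.97. Hepatocyte genes had a median of 0.23 (percentile 99.3) and photoreceptors of 0.17 (percentile 98.6). The complement and acute phase list, at 0.19 (percentile 95.3), lay inside the central 95%. Keratinocyte genes had a median of -0.15 (percentile 0.30), with keratin 13 at 5178 and 4282 FPKM, skeletal muscle of -0.08 (percentile 0.01) and ribosomal proteins of -0.05 (percentile 1.48), with RPL5 at 792 and 585 FPKM. By main contig, the annotations with the highest step were TMEM108 (0 and 14.1 FPKM), PSMC3IP (0 and 7.93), PCDHGA12 (0 and 7.29), the slime mould NADH dehydrogenase match (0 and 6.14) and the sugar transferase OGT (0 and 5.66). Those with the lowest step, all listed at 0 at 100 mg/L, were the poly(A)-binding protein PABPC4 (68.7 FPKM at 10 mg/L), PKD1 (17.2), BTAF1 (12.2), Xfin (12.1) and CISH (10.1). The main contig of PABPC4 was at 39.9 FPKM in the control and listed at 0 in the surfactant control. Summed over all contigs, all 5 of each were past 2-fold, but 2 of the 5 lowest were at 0 at 100 mg/L and PKD1 was at 3.73 FPKM. In all, 3657 contigs were at least 2-fold higher and 3315 lower at 100 than at 10 mg/L, a balance that turned with median-of-ratios scaling, to 3406 and 3494.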

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

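The alternatives with a mean of at least 20 FPKM, with FPKM summed per annotation, with the control shared by both concentrations and with other proteins left out were chosen after the data were seen, as was 1 contig per annotation for the counts against both libraries without fibres. Both scalings and both pseudocounts left every count past 2-fold within 1.5 times the reported one, and no scaling moved the share of higher contigs by over 10 percentage points. The other settings change how many contigs are tested or the threshold itself, which accounts for the direction of the change. In the order surfactant control against control, PET 10 and PET 100 mg/L against surfactant control, PET 10 and PET 100 mg/L against control, and PET 100 against PET 10 mg/L, the counts past 2-fold were 56588, 62039, 63745, 58730, 60511 and 64383 with no filter, 442, 504, 626, 504, 564 and 478 with a mean of at least 5 FPKM, 2789, 3496, 3293, 2932, 2786 and 3425 at 4-fold, 267, 268, 291, 273, 274 and 261 with 1 contig per annotation, 26, 34, 42, 25, 35 and 34 with FPKM summed per annotation and a mean of at least 5, and 33, 41, 78, 54, 89 and 57 with a mean of at least 20 FPKM. For contigs past 2-fold from both libraries without fibres at 10 mg/L, at 100 mg/L and at both, the counts were 28742, 29717 and 9194 with no filter, 197, 250 and 56 with a mean of at least 5, 1352, 1195 and 523 at 4-fold, 119, 126 and 33 with 1 contig per annotation, 10, 13 and 3 with summed annotations, and 18, 38 and 12 with a mean of at least 20. Between the concentrations the balance of higher and lower, 3657 and 3315, turned to 3406 and 3494 with median-of-ratios scaling, 3394 and 3508 with upper quartile scaling, 1651 and 1774 at 4-fold, and 27 and 30 with a mean of at least 20. The share higher moved by over 10 points in 2 cases: of contigs past 2-fold, 42.3% were higher at PET 100 mg/L than in the surfactant control with a mean of at least 20 FPKM, and 72.0% at PET 10 mg/L than in the control with summed annotations.

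The correlation of the PET ratios was 0.011 and 0.003 with references apart, which removes the shared library, 0.554 with a mean of at least 5 FPKM and 0.424 with the control shared; the cause of the last pair of shifts was not tested. At 10 mg/L, 3 lists lay outside the central 95%, against 7 with the untreated control as reference and 5 with 1 contig per annotation. The median of the thyroid list at 100 mg/L, -0.28, turned to 0.053 with a mean of at least 5 FPKM and to 0.004 with 1 contig per annotation, and that of the heat shock list at 10 mg/L, -0.14, to 0.012 with other proteins left out, which shows that those proteins gave the sign; for the thyroid list the cause was not tested. Over all lists, both concentrations and 8 settings, 109 other list medians moved by more than 1 SD of random lists and 400 did not. Complement and acute phase stayed outside the central 95% at both concentrations, and skeletal muscle and keratinocytes at 100 mg/L did so except that keratinocytes lay at percentile 18.98 with no filter. Contigs with low values were past 2-fold most often: from 1 to 2 FPKM, 26.5% of contigs were so between the libraries without fibres. Depth itself was not tested as the cause. No paired analysis was possible because each group held 1 library.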

Other observations

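The tests and counts in these observations were chosen after the results were seen. When FPKM was summed over the contigs of each annotation, 39 of 2692 annotations with a mean of at least 10 FPKM had both PET libraries at least 1.25-fold from both libraries without fibres, 26 higher and 13 lower. The other pairings of the 4 libraries gave 14 and 12; only these 3 pairings exist, too few to place a share on the first. The mitochondrial uncoupling protein UCP2 was at 297 and 267 FPKM without fibres and at 460 and 445 at 10 and 100 mg/L. Also among the 26 higher were hpd (94.3, 96.8, 131 and 140 FPKM in the order control, surfactant control, 10 and 100 mg/L), TAT (94.2, 82.9, 131 and 126), the hepatocyte transcription factor hnf4a (14.5, 14.1, 19.7 and 19.1), apolipoprotein A-I (10.53, 13.5, 19.4 and 18.6) and CYP1A1 (37.6, 30.5, 53.2 and 52.1). Among the 13 lower were the glutathione transferases GSTM1 (459, 556, 337 and 308 FPKM) and GSTO1 (54.8, 66.4, 39.5 and 42.2), prostaglandin reductase PTGR1 (104, 133, 69.2 and 63.7), the ribosomal protein RPL11 (1646, 1599, 1038 and 1096), the DNA damage gene GADD45B (65.3, 66.1, 48.8 and 47.4) and KLF2 (104, 99.5, 78.1 and 73.0). By the same sums, the iron hormone hepcidin (hamp1) was at 4.79, 2.57, 4.76 and 10.9 FPKM and the lectin ladderlectin at 14.4, 17.8, 8.82 and 4.36.

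Of 165 contigs with a mean of at least 1000 FPKM, 5 ranged over at least 2-fold among the libraries, and they went together. The one with an annotation, NLRC3, was at 2714 FPKM in the control, 4895 in the surfactant control, 5315 at 10 mg/L and 1071 at 100 mg/L. The unannotated TR65613|c0_g1_i1 was at 6326, 11319, 12797 and 3016. The 5 contigs held 1.76% of the FPKM in the control, 3.11% in the surfactant control, 3.46% at 10 mg/L and 0.76% at 100 mg/L.

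The median of the complement and acute phase list was higher in both PET libraries than in either library without fibres. An explanation was taken as argued against only past 2 SD both of random lists and of the lists' own members, drawn with replacement. For scaling, random lists alone had first been tried and argued against it at both concentrations, and the rule was then revised. The draws took contigs as independent, but the 14 of the complement list fall to 8 with 1 contig per annotation. The SD of the members can therefore be understated. Scaling as the cause would move contigs of like level as much. By the rule it is argued against at 100 mg/L, but by a narrow margin for the members. The list median there exceeded that of random lists by 0.34 against the surfactant control (4.19 and 2.08 SD). By the same bounds scaling stays open at 10 mg/L, where the excess was 0.21 (2.90 and 1.58 SD). Median-of-ratios scaling nonetheless left the list median there at 0.20 (percentile 99.45). It moved the median of all contigs by -0.021, so scaling of that size accounts for little of the excess. More liver RNA than in the surfactant control stays open by the same rule, although the hepatocyte list, which shares 0 contigs with this one, had medians of -0.09 at 10 mg/L (percentile 3.12) and 0.09 at 100 mg/L (percentile 61.5): it lay below the complement median by at least 0.32, which is 3.39 and 3.04 SD of random lists but 1.92 and 1.81 SD of the members. Of its 27 contigs, 6 were at least 1.25-fold higher and 8 lower at 10 mg/L, and 7 and 4 at 100 mg/L. Its members hpd and apolipoprotein A-I were among the sums higher in both PET libraries. Against the untreated control the gap between the medians of the complement and hepatocyte lists was 0.20 at 10 mg/L (1.98 SD of random lists and 0.83 SD of the members). At 100 mg/L it was 0.31 (2.71 and 1.47 SD), past 2 SD of random lists only. The hepatocyte list was itself higher, so by the rule more liver RNA could account for the difference there. An acute phase response to the fibres stays a hypothesis: 9 of the 14 contigs were higher in both PET libraries than in both without fibres, but 1 library per group cannot separate exposure from other differences between the larvae sampled, and the surfactant control was also higher than the control. Which of these holds cannot be told apart without further libraries.

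About as many contigs were past 2-fold between the libraries without fibres as between either and a PET library. Few reads at low levels may account for most of them, since the share past 2-fold between the libraries without fibres was 26.5% from 1 to 2 FPKM and 0.86% at 20 FPKM or more. At that level the PET libraries exceeded the surfactant control's count by at least 1.24 times (41 and 78 contigs against 33), and whether exposure or another difference between single libraries lies behind it stays open.

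Stanniocalcin was lowest in the surfactant control. Of 7872 contigs within 1.5-fold of its mean, 2.90% differed as much between the libraries without fibres and 1.99% as much between PET 100 mg/L and the surfactant control, which leaves counting error at its level open. A response to the fibres was not separable from the low value of the surfactant control: against the untreated control the log2 ratio was -0.80 at 10 mg/L and 0.35 at 100 mg/L. An effect of Tween 80 could give the low value as well.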
